A study of Homo sapiens with 12 samples.

How the data were processed

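Immunoprecipitated RNA (m5C MeRIP-seq, 6 libraries) and input RNA (6 libraries) came from HK2 cells treated with cisplatin, with or without silencing of NSUN7. Total RNA was extracted with Trizol and made into TruSeq libraries, per the labels' protocols. FastQC, cutadapt 1.9.3, STAR, HISAT2 2.0.4 and the build hg38 are named in the submitters' processing notes, without their roles. The peak identifiers in the lists carry the name MACS; its version, its settings and the use of the input libraries are not given in the sources used here.

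Each deposited list gives, per peak, its position, length, gene, transcript, score, fold enrichment and FDR. The score is 10 times the negative log10 of the caller's p-value, per the file headers, and the authors listed peaks from a score of 50 (p of 1e-05) upward. A score of 3100 was shared by 2061 peaks and acts as a ceiling. The fold enrichment is a linear ratio computed by the authors' peak caller. The deposited FDR has no unit in its header and was read as a percent, because its values are too large for a fraction. All of them are each list's own values. Peak length equalled end minus start for every peak, so starts were read as counting from 0 and are given here counting from 1. Many peaks end at the same base in several lists (4467 peaks have identical borders in all 6), and some are a few bases long, down to 1. From 51.7% to 57.8% of the caller's peak numbers appear in a list, so peaks had been filtered before deposit by a step that the sources do not state. In each list 1 line was not analysed here. All per-sample columns were matched to their sample by name.

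Peaks from the 6 lists were merged wherever they overlapped by at least 1 base, without strand, into 31781 regions, of which 32 hold peaks of more than 1 gene. A library occupied a region or a gene where it had at least 1 peak there. Gene names are the authors'. Of 10007 symbols, 9975 matched a RefSeq symbol, identifier or synonym (GRCh38.p14), and 99.5% of their peaks overlapped the gene's RefSeq span. Place in exon, intron or UTR was not analysed here, because no exon annotation was used. Neighbouring peaks of a gene may therefore be parts of 1 stretch of spliced RNA, and each was counted as listed. The tests planned for values per gene or per site were not used, since the lists hold peaks; those for peak lists were used as planned, except the place of peaks in transcripts.

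Peaks, genes, covered length and median length per library were compared by exact two-sided permutation tests of 3 libraries against 3, with Benjamini-Hochberg adjustment over the 4 measures. Regions and genes present in all 3 libraries of one group and in 0 of the other were counted for the real division of the libraries and for the other 9. Gene lists and annotation terms (at least 10 genes with a peak) were tested by two-sided Fisher's exact tests against all genes with a peak, adjusted over lists and directions at an FDR of 0.05. Some genes belong to several lists. The 16 lists cover the study's 3 genes, m5C writers, m5C readers and erasers, inflammatory cytokines and NF-kB targets, HMGB1 receptors and TLR signalling, extracellular matrix and TGF-beta, p53 targets, tubular injury, cell death, proximal tubule, ribosomal proteins, mitochondrially encoded genes, and endothelial, leukocyte, fibroblast and distal nephron markers.

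The genes to name were fixed by rule before the data were examined. They are NSUN7, SPARC and HMGB1; the 10 genes of each direction with the highest mean within-list percentile of their best peak's p; up to 4 members of each list, first those in one group alone and then those with the largest difference in occupied libraries; and the 5 genes per direction with the most regions in one group alone. Genes without a symbol were left out, and some genes that the rule picks are not reported here. Exceptions are stated where they occur. Alternatives were a score minimum of 60, a fold of at least 3.54 (2 times the smallest fold), equal list lengths (the best 14964 peaks by p), coverage of at least 50% of a region, presence in at least 2 of 3 libraries, another background for the lists, replicate blocks, and leaving out each library. The counting step was tested on simulated lists built from the real occupancy of 31734 regions: of 200 planted regions per direction, 100% were recovered in each, as the condition requires, and 177 and 182 unplanted regions met the condition by chance. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

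Read depth is unknown, and a missing peak can reflect low RNA, low depth or weak enrichment as well as the absence of m5C. No input value was analysed here, so RNA level and methylation are not separated.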

Results

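The series profiled 5-methylcytosine (m5C) in RNA of HK2 cells, an immortalised line of human kidney proximal tubule epithelium. RNA fragments were captured with an antibody against the modified base and sequenced beside unselected input RNA. All cells had received cisplatin, a DNA-crosslinking drug that injures the tubule. In 1 group NSUN7, a member of the NOL1/NOP2/SUN family of RNA methyltransferases, had also been silenced. Of the 12 samples, 6 were immunoprecipitates and 6 were inputs, with 3 replicates per condition in each kind. The processed values consisted of 6 peak lists, 1 for each immunoprecipitate, and no input values were analysed here. Peaks had been called in each library separately, so presence of a peak was compared between lists, and the score, fold and FDR of a peak served only to describe or rank it within its own list. Sequencing depth is unknown from these lists. The labels do not say whether replicates were separate cultures, so p-values from permuting libraries measure only the spread between these samples. Fisher's tests and permutations of genes do not measure that spread. Comparisons of 3 libraries with 3 cannot reach an exact permutation p below 0.1.

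The labels name NSUN7, SPARC and HMGB1 as the genes at the centre of the study. HMGB1, a nuclear DNA-binding protein that acts as an inflammatory alarm signal once released, carried 1 peak in each of the 6 lists. The peak covered the same 170 bases of chromosome 13 (30465796 to 30465965, hg38) in every list. Identical borders in all 6 lists were common (4467 peaks) and need not mark a precise site. Its authors' fold enrichment was 10.04 ± 1.28 (SD, n = 3) in the cisplatin lists and 9.46 ± 2.30 (SD, n = 3) in the knockdown lists. It stood at a mean percentile of 99.1 ± 0.619 (SD, n = 3) by p within the cisplatin lists and 95.8 ± 1.93 (SD, n = 3) within the knockdown lists. These are ranks within separate lists and do not measure a change. For SPARC, a secreted matrix glycoprotein, 0 peaks were listed in the 6 libraries, and 0 peaks of any gene lay in its RefSeq span on chromosome 5 (151661096 to 151686915). NSUN7 likewise had 0 listed peaks and 0 peaks in its span on chromosome 4 (40749955 to 40811184). A peak list shows no RNA level, so the silencing of NSUN7 was not checked here, and 1 line of each list was not analysed here.

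The first comparison asked whether silencing NSUN7 went with fewer or shorter peaks. The cisplatin lists held 15978 ± 933 peaks (SD, n = 3) and the knockdown lists 15142 ± 171 (SD, n = 3), a mean difference of -836 peaks (exact two-sided permutation p = 0.3). Peaks lay in 7194 ± 208 genes (SD, n = 3) per cisplatin library and in 6698 ± 190 genes (SD, n = 3) per knockdown library. That difference of -496 genes, or -6.89%, separated the groups completely, from 6964 to 7370 genes against 6493 to 6868 (exact permutation p = 0.1, the smallest possible; Benjamini-Hochberg adjusted 0.2 over 4 measures). Peaks covered 5.85 ± 0.464 megabases (SD, n = 3) against 5.51 ± 0.322 megabases (SD, n = 3), with an exact permutation p of 0.4. The median peak was 199 ± 1.15 bases long (SD, n = 3) in the cisplatin lists and 194 ± 1.73 bases (SD, n = 3) in the knockdown lists (exact permutation p = 0.1, adjusted 0.2). This exact test cannot pass a threshold of 0.05 with 3 libraries against 3. Of the 93361 peaks in the 6 lists, 7 had an authors' FDR, read as a percent, of 5% or less. For 876 peaks it was 20% or less, so the lists rest on the p threshold. The median FDR of a list ran from 54.5% (CIS replicate 2) to 71.1% (KD_CIS replicate 3). Read this way, a large share of the listed peaks may be false, including peaks named below. Without CIS replicate 2, the longest list, the mean difference was -343 peaks and -0.0797 megabases.

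**Figure D1:**
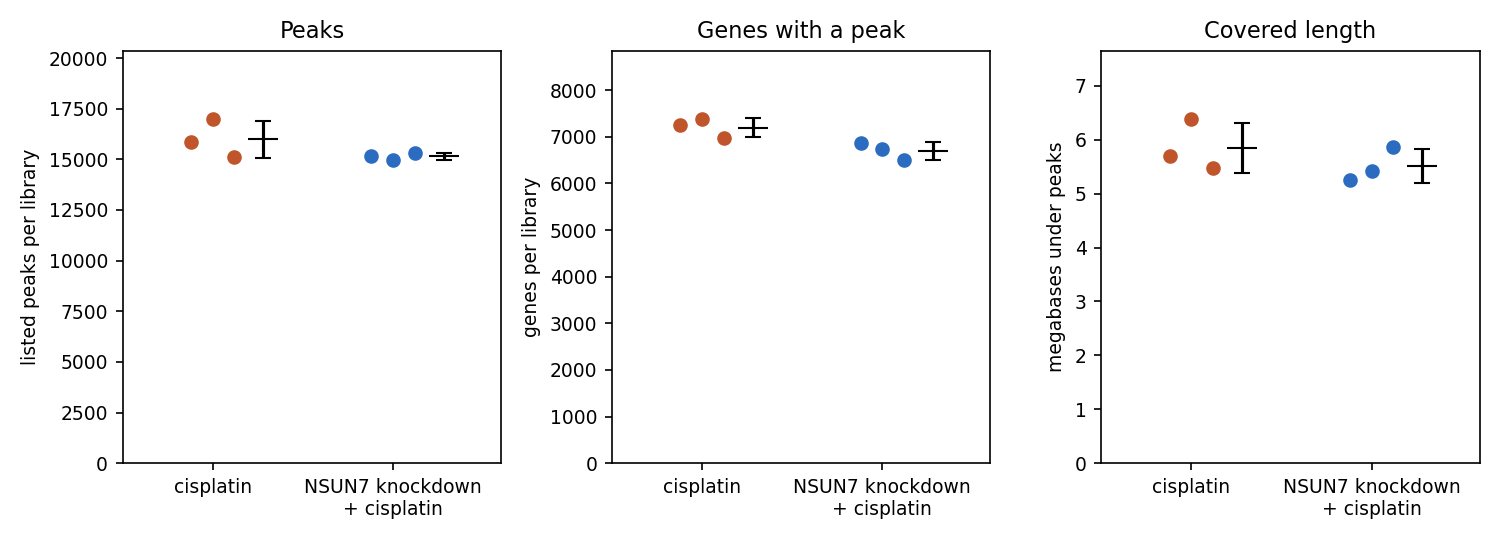
Number of listed peaks, number of genes with a peak and megabases under peaks per library, for cisplatin (orange) and NSUN7 knockdown with cisplatin (blue); each point is 1 library, and the bar beside it gives the mean and SD of 3. Genes with a peak do not overlap between the groups (6964 to 7370 against 6493 to 6868), whereas peaks and covered length do.

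The second comparison asked which stretches of RNA carried a peak in one condition alone. Overlapping peaks were merged into 31781 regions, of which 5875 had a peak in all 6 libraries and 11515 in a single library. A peak in all 3 cisplatin libraries and in 0 knockdown libraries was found for 426 regions. The opposite was found for 235 regions. Leaving out KD_CIS replicate 1, which lets 2 knockdown libraries meet the condition, gave 667 and 648 regions. By the lowest score over their 3 lists, the first of the cisplatin-alone regions lay in PTMS, which encodes parathymosin (chromosome 12, 6766375 to 6766750), and in MYLK, which encodes myosin light chain kinase (chromosome 3, 123700020 to 123701005). Both had a score of 3100 in each cisplatin list. Regions of the collagen genes COL5A1 (chromosome 9, 134812605 to 134812712) and COL4A1 (chromosome 13, 110187138 to 110187329) followed, with scores from 3025 to 3100 and from 2037 to 3100. In the knockdown direction the first lay in PRDM1, a transcriptional repressor (chromosome 6, 106086320 to 106086595; scores from 616 to 1206), and in the laminin gene LAMC1 (chromosome 1, 183130344 to 183130549; scores from 506 to 2365). These 6 regions were singled out after their values were seen. A region found in one group alone does not mean that its gene lacked peaks in the other group: 484 of the 661 lay in genes with a peak in at least 1 list of the other group. PTMS, MYLK, COL5A1, COL4A1 and LAMC1 each had peaks in all 6 libraries, and PRDM1 had one in 1 cisplatin library. In PTMS, all 3 knockdown lists and 1 cisplatin list held a peak within 10 kilobases of the first, at 6770392 to 6770952. Most regions found in one group alone were weak: the lowest of the 3 scores was under 100, against a listing threshold of 50, for 301 of the 426 regions and for 190 of the 235. Among regions with a peak in all 6 libraries, the lowest of the 6 scores was under 100 for 1785 of 5875. That lowest score is taken over 6 lists in place of 3, so the shares are not strictly alike. Across the 10 ways of dividing the 6 libraries into 3 and 3, the real division gave 661 regions in one set of 3 alone and the highest of the other 9 gave 390. So few divisions cannot give a share under 0.05. Libraries of one group shared on average 48.5% (cisplatin) and 47.9% (knockdown) of the regions that either of a pair occupied, against 46.1% for pairs from different groups (difference of 2.07 percentage points; exact permutation p = 0.1 over the 10 divisions).

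**Figure D2:**
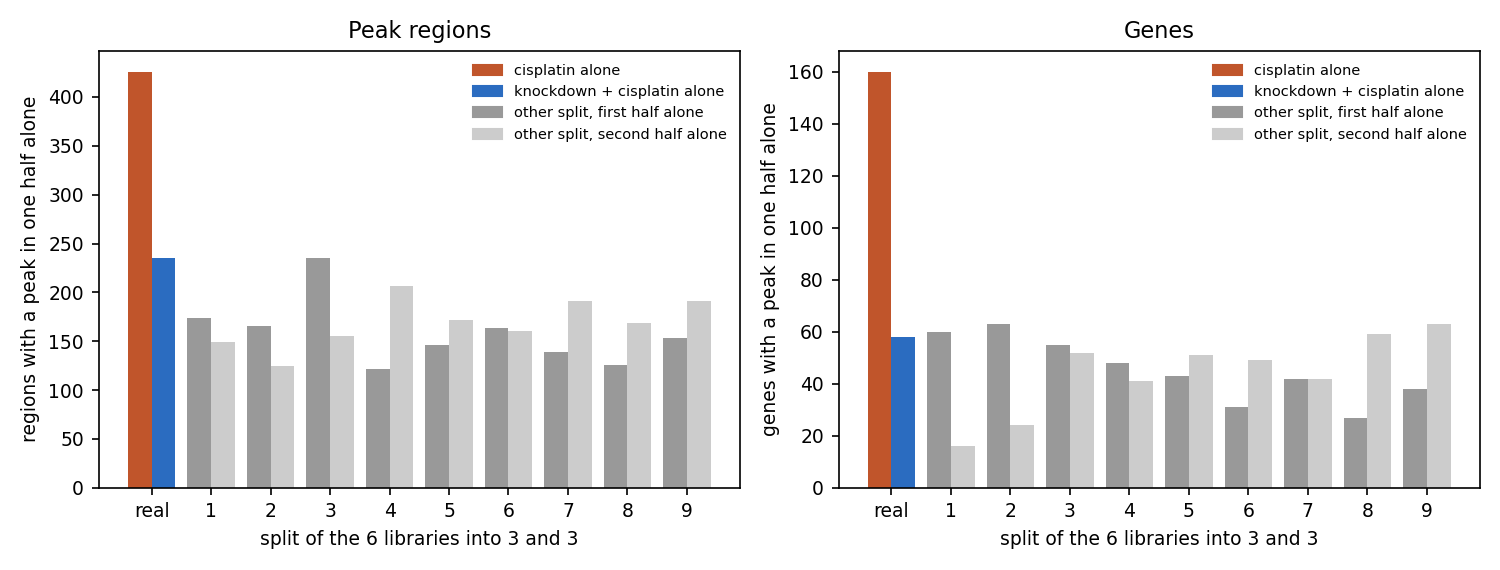
Number of regions (left) and genes (right) with a peak in all 3 libraries of one set and in 0 of the other set, for the real division of the 6 libraries (orange, cisplatin alone; blue, knockdown alone) and for each of the other 9 divisions (greys). The real division gives 426 and 235 regions and 160 and 58 genes; in the other divisions a single set gives 122 to 235 regions and 16 to 63 genes.

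At the level of genes, 160 of the 10007 genes with any peak had one in all 3 cisplatin libraries and in 0 knockdown libraries, and 58 had the reverse. Leaving out 1 library, which shortens the list of conditions, gave 241 to 306 and 109 to 126 genes, and a score of at least 200 in all 3 lists gave 14 and 0. The highest of the other 9 divisions gave 107 such genes against 218 in the real one. By mean percentile of the best peak, the first of the 160 was CXCL1, a chemokine that attracts neutrophils. Its single peak spanned 722 bases of chromosome 4 (73870521 to 73871242) in each cisplatin list, with a fold of 6.44 ± 0.620 (SD, n = 3) and a percentile of 88.2 ± 1.81 (SD, n = 3). RSPO3, a secreted enhancer of Wnt signalling, followed with a fold of 11.1 ± 3.71 (SD, n = 3). HIC1, a transcriptional repressor, had a fold of 7.06 ± 1.43 (SD, n = 3) over a peak of up to 6571 bases. CDKN1A, which encodes the cell cycle inhibitor p21, had a fold of 10.5 ± 3.17 (SD, n = 3). The region its cisplatin lists shared lay at chromosome 6, 36678710 to 36678939. Each fold is that of a list's best peak. For RSPO3 and CDKN1A that peak lay elsewhere in CIS replicate 1 than in replicates 2 and 3. The matrix collagen gene COL5A3 carried 22 peaks over the 3 cisplatin lists and 0 over the knockdown lists. The other 5 of the 10 were SIX5, SDCBP2, SBSN, BRMS1 and CACNA1G. The best peak of SDCBP2 was 3 bases long or shorter in every cisplatin list, and in BRMS1 the lists placed their peaks at different positions, so that 0 of its regions was common to the 3.

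Among the 58 genes with peaks in the knockdown lists alone, STC1 ranked highest. STC1 encodes the secreted glycoprotein stanniocalcin 1, and its peak lay at chromosome 8, 23854406 to 23854807, with a fold of 7.42 ± 1.09 (SD, n = 3) and a percentile of 73.1 ± 15.2 (SD, n = 3). MYCN, a transcription factor of the MYC family, had a fold of 9.75 ± 0.800 (SD, n = 3). KALRN, a guanine nucleotide exchange factor, carried 24 peaks in the 3 knockdown lists and 0 in the cisplatin lists. ZC3H12A, a ribonuclease that degrades inflammatory transcripts, and CDK12, a kinase of transcription elongation, had peaks in all 3 knockdown lists, but 0 of their regions was common to those lists. PLEKHA6 was also among the 10. The remaining 4, ELOA3B, SPIN2B, POTEJ and F8A3, belong to families of near-identical copies, where the assignment of reads to a copy is uncertain. With a score minimum of 60 in place of 50, F8A3 kept its peak in 2 of the 3 knockdown lists.

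**Figure D3:**
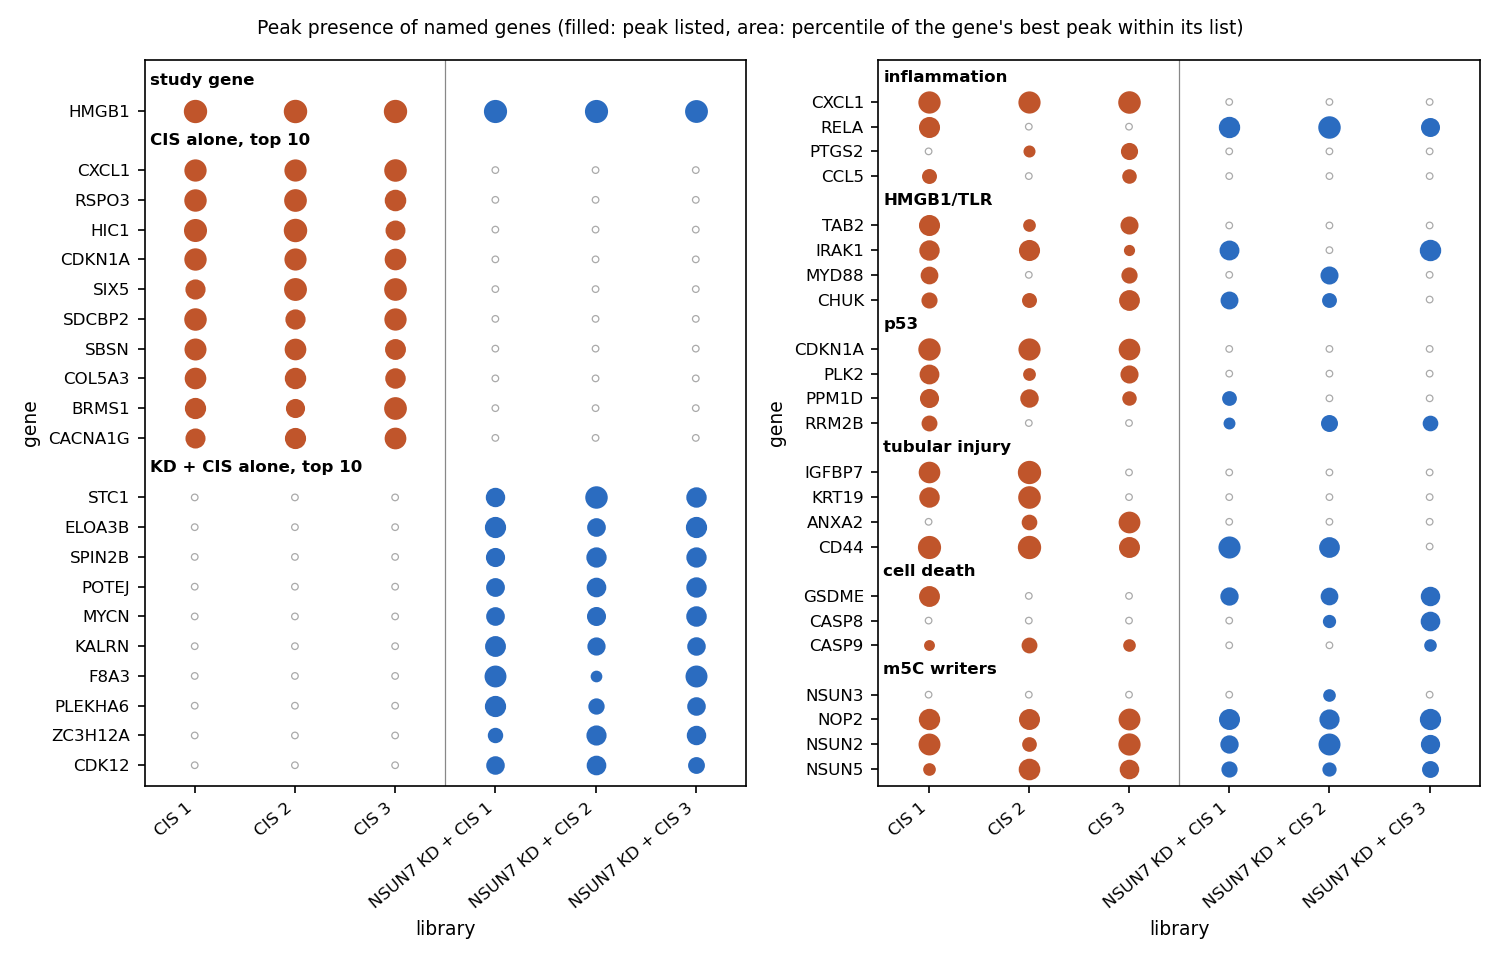
Peak presence in each of the 6 libraries (columns; orange, cisplatin; blue, NSUN7 knockdown with cisplatin) for HMGB1, the 10 top-ranked genes of each direction and members of 6 gene lists (rows). A filled circle marks a listed peak, its area the percentile of the gene's best peak within that list, and an open circle a library with 0 peaks; HMGB1 is filled in all 6 columns and CXCL1 in the 3 cisplatin columns.

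Several genes held more than 1 region of the same direction. ABI3BP had 11 of its 21 regions in the cisplatin lists alone, between 100775207 and 100850119 of chromosome 3. These 11 regions were 63 to 129 bases long. ABI3BP carried 17.0 ± 1.73 peaks (SD, n = 3) per cisplatin library and 1.00 ± 1.00 (SD, n = 3) per knockdown library. CACNA1G, which encodes a T-type calcium channel subunit, had 9 of 16 regions in the cisplatin lists alone, with 13.0 ± 1.00 peaks (SD, n = 3) against 0 in each knockdown library. LAMC3, a laminin chain of the basement membrane, had 14.7 ± 0.577 peaks (SD, n = 3) against 3.33 ± 1.15 (SD, n = 3), and 5 of its 19 regions were in the cisplatin lists alone. MYLK had 7.33 ± 0.577 peaks against 1.33 ± 0.577 (SD, n = 3 each), and RIPOR3 had 6 ± 1 against 3 ± 1 (SD, n = 3 each). In the other direction, CYFIP2, a subunit of the actin-regulating WAVE complex, had 8.33 ± 0.577 peaks (SD, n = 3) per knockdown library against 1.00 ± 1.00 (SD, n = 3) per cisplatin library. AMOT, KALRN, NBPF19 and PREX1 each had 3 regions in the knockdown lists alone. PREX1, an activator of Rac, carried 22.0 ± 2.65 peaks (SD, n = 3) against 14.3 ± 0.577 (SD, n = 3), and NBPF19 belongs to a repeated gene family. For each of these 10 genes the peak numbers of the groups did not overlap (exact permutation p = 0.1, the smallest possible), but the genes were picked for a difference in peaks. Peaks were counted along the genome without exon positions, so neighbouring peaks of a gene may belong to 1 stretch of spliced RNA.

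**Figure D4:**
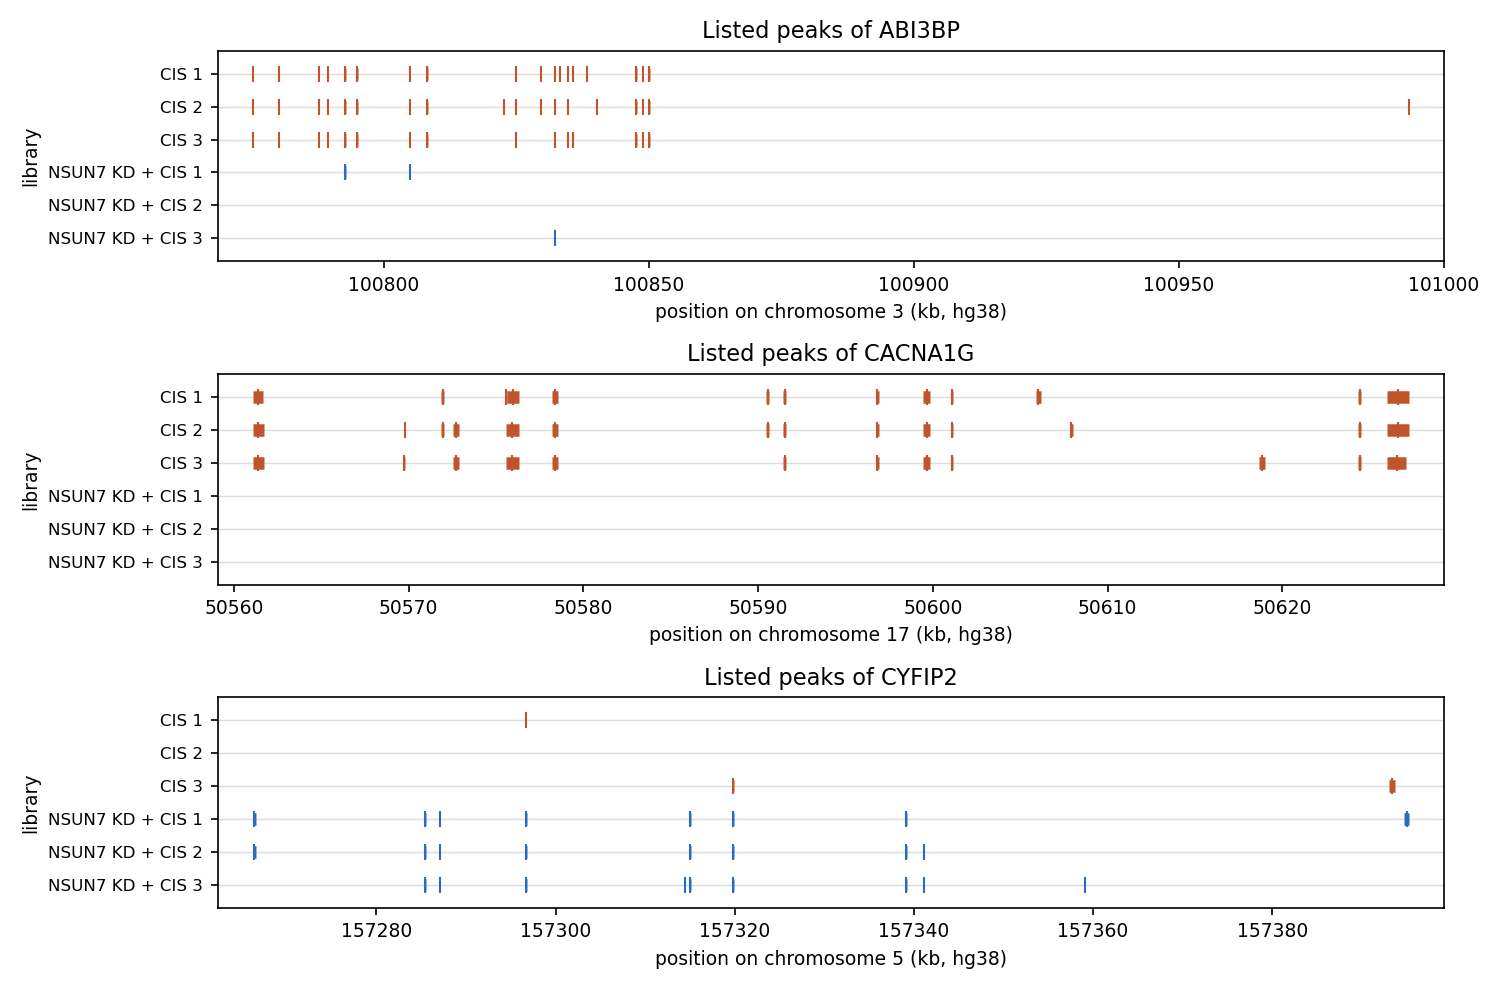
Listed peaks of ABI3BP (chromosome 3), CACNA1G (chromosome 17) and CYFIP2 (chromosome 5) along the genome in kilobases (hg38), with 1 row per library (orange, cisplatin; blue, NSUN7 knockdown with cisplatin) and 1 mark per peak. The 3 cisplatin rows of CACNA1G hold 12 to 14 peaks each and its knockdown rows 0; CYFIP2 has 8 or 9 peaks in each knockdown row and 0 to 2 in each cisplatin row.

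The gene lists fixed beforehand were compared with all genes that had a peak. Of 28 tests over 14 lists and both directions, 0 passed Fisher's exact test after Benjamini-Hochberg adjustment, and 1 had an unadjusted p under 0.05. That list was the p53 targets, the genes that the tumour suppressor p53 switches on after DNA damage. Of its 20 members with a peak, 2 had peaks in the cisplatin lists alone, against 160 of 10007 genes (Fisher's exact p = 0.040, adjusted 1; with presence in at least 2 of 3 libraries p = 0.273). In all, 6 of the 20 had peaks in more cisplatin and 6 in more knockdown libraries, with 13.7 ± 0.577 members (SD, n = 3) against 12.3 ± 2.31 (SD, n = 3) per library (exact permutation p = 0.4). The 2 members found in the cisplatin lists alone were CDKN1A and PLK2, a kinase induced by p53. PPM1D, a phosphatase that damps the p53 response, had a peak in 3 cisplatin and 1 knockdown libraries, and RRM2B, a ribonucleotide reductase subunit, in 1 and 3.

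Among 16 inflammatory cytokines and NF-kB targets with a peak, CXCL1 was the 1 member found in the cisplatin lists alone (Fisher's exact p = 0.227, adjusted 1). PTGS2, the inducible cyclooxygenase, and the chemokine CCL5 had peaks in 2 cisplatin libraries and 0 knockdown libraries, and the NF-kB subunit RELA in 1 and 3. In all, 8 of the 16 members had peaks in more cisplatin than knockdown libraries and 1 in fewer. Counted per library, 12 ± 1 members (SD, n = 3) had a peak in the cisplatin libraries and 8.67 ± 0.577 (SD, n = 3) in the knockdown libraries (exact permutation p = 0.1, adjusted 0.467 over 14 lists). The tubular injury list, which gathers genes raised in damaged tubules, had 8.33 ± 1.53 members (SD, n = 3) with a peak against 5.33 ± 0.577 (SD, n = 3), also with an exact permutation p of 0.1 and an adjusted value of 0.467. Its members KRT19, IGFBP7 and ANXA2 had peaks in 2 cisplatin libraries and 0 knockdown libraries, and CD44, a hyaluronan receptor, in 3 and 2. For HMGB1 receptors and Toll-like receptor signalling the numbers were 9 ± 0 members (SD, n = 3) and 7.33 ± 0.577 (SD, n = 3), with an exact permutation p of 0.1 and an adjusted value of 0.467. In that list TAB2, an adaptor of the kinase TAK1, was found in the cisplatin lists alone. IRAK1 and CHUK had peaks in 3 and 2 libraries and MYD88 in 2 and 1, and with a score minimum of 60 the difference for IRAK1 was 0. Over all 10007 genes, 28.7% had peaks in more cisplatin than knockdown libraries and 18.6% in fewer, so that part of each list's difference is shared with genes in general. The counts per library were an addition made after the data had been examined.

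The m5C writers other than NSUN7 showed little difference in peak presence: 4 of the 5 members with a peak had one in equal numbers of cisplatin and knockdown libraries. NOP2, NSUN2 and NSUN5 carried peaks in all 6 libraries, and NSUN3 in a single knockdown library. Among 8 m5C readers and erasers, 4 had peaks in more cisplatin libraries, including the reader ALYREF (3 and 2) and the demethylase TET1 (1 and 0). FMR1, another reader, had 3 and 2, and ALKBH1, a demethylase, had 2 and 3. Of 20 extracellular matrix and TGF-beta genes, 15 had a peak in all 6 libraries. The integrin subunit ITGA5 had one in 3 and 1 libraries, LAMB1 in 3 and 2, COL1A2 in 1 and 0 and COL3A1 in 1 and 2. Cell death genes were mixed, with 4 of 16 in more cisplatin and 5 in more knockdown libraries. CASP9 had a peak in 3 and 1 libraries, CASP8 in 0 and 2, and the pore-forming GSDME in 1 and 3.

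Of 86 cytosolic ribosomal protein genes, 29 had a peak, in 19.0 ± 4.36 (SD, n = 3) members per cisplatin library and 19.3 ± 2.08 (SD, n = 3) per knockdown library (exact permutation p = 1). RPS29 had peaks in the cisplatin lists alone, but at another position in CIS replicate 3 than in replicates 1 and 2. RPLP1 had peaks in 2 cisplatin lists and 0 knockdown lists, and RPS15 in 1 and 2. These genes have many processed copies in the genome, so their read assignment is uncertain. Proximal tubule markers were sparse, with 3 of 18 listed: the brush border peptidase ANPEP (3 and 2 libraries), SLC13A3 (2 and 2) and SLC4A4 (1 and 0). Of the markers of other cell types, the endothelial list had 2 of 7 members with a peak (TEK in 3 and 2 libraries, a difference lost with a score minimum of 60 or equal list lengths, and KDR in 1 and 0). CD14, seen in 1 cisplatin library, was the single leukocyte marker of 8, and 4 of 9 fibroblast markers had peaks, including ACTA2 in all 6 libraries and THY1 in 1 and 1. None of the 8 distal nephron markers and none of the 13 mitochondrially encoded genes had a listed peak. Terms of the authors' pathway and Gene Ontology annotation were tested in both directions by Fisher's exact test, and 0 of 2062 tests passed after Benjamini-Hochberg adjustment, with 40 at an unadjusted p under 0.05.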

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

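The minimum score of 200 and the restriction to RefSeq-matched genes were chosen after the data had been seen. Mean peaks, genes, covered length and median length per library were lower in the knockdown group under each alternative run. The difference was -767 peaks with a score minimum of 60 and -622 with the fold minimum, with exact permutation p from 0.1 to 0.5 over all alternatives, and from -1270 to -343 peaks when a library was left out. For genes it was -485 and -476, and -611 to -393. Deviations of same-numbered libraries correlated at -0.0197 to -0.00693 over regions, and each library correlated lowest with its own number. These values give no sign of pairing but cannot settle it, since the labels do not say what equal numbers mark. As a block, the differences of -836 peaks, -496 genes, -0.340 megabases and -5.33 bases had exact sign-flip p of 0.5, 0.25, 0.5 and 0.25, where 0.25 is the smallest possible.

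Regions in the cisplatin lists alone numbered 426 and in the knockdown lists alone 235; a score minimum of 60, equal list lengths and 50% coverage left both within 1.5 times. Presence in at least 2 of 3 libraries gave 1695 and 1365 regions and 512 and 244 genes, in place of 160 and 58 genes. A score of at least 200 in all 3 lists gave 42 and 5 regions and 14 and 0 genes. Leaving out 1 library, which shortens the list of conditions, gave 640 to 931 and 396 to 648 regions and 241 to 306 and 109 to 126 genes. The cisplatin count was the higher of the pair under each of these settings, but for regions by only 667 to 648 without KD_CIS replicate 1. Among gene lists, 0 tests passed in the main analysis, with presence in at least 2 of 3 libraries, and with a background of genes found in at least 3 libraries. With presence in at least 2 of 3, the smallest p was that of the tubular injury list (3 of 11 members, Fisher's exact p = 0.016, adjusted 0.452). Of 64 named genes with unequal presence, 60 kept their direction and their place in one group alone or outside it with a score minimum of 60, and 62 did so with equal list lengths. The exceptions were F8A3 and KLF6 (2 and 1 knockdown libraries with a score minimum of 60), PELI2 (2 cisplatin libraries with equal lists), IRAK1 (a difference of 0 with a score minimum of 60) and TEK (0 under both).

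Alternatives for the place of peaks in transcripts, for values per gene (IP, input and their ratio), for methylation per site and for list tests on values per gene were not run, because the lists hold neither such values nor exon annotation. Depth is unknown, and it limits every statement on a missing peak.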

Other observations

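The comparisons with other divisions of the libraries, the score limits of 100 and 200, the search for opposite regions of the same gene and the count of genes with 3 or more regions were chosen after the results were seen; the tests with equal list lengths and at other regions of the same genes were set before their results were seen. The genes of the next paragraph were picked after their values were seen.

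Some further genes outside the named ones had peaks in all 3 cisplatin libraries and 0 knockdown libraries. OSMR, the oncostatin M receptor, had 1 peak at chromosome 5, 38845999 to 38846387, with a fold of 4.85 ± 0.448 (SD, n = 3). IRAK2, a kinase of interleukin 1 and Toll-like receptor signalling, had a fold of 6.35 ± 0.586 (SD, n = 3) and low scores of 84.6 to 89.4 at each list's best peak. That peak lay elsewhere in CIS replicate 3. The IRAK2 region common to the 3 cisplatin lists (chromosome 3, 10234459 to 10234659) scored 59.7 to 87.4. PELI2, a ubiquitin ligase of the same pathway, had 2 regions in the cisplatin lists alone, as did MMP9, a matrix-degrading protease with a fold of 10.9 ± 6.49 (SD, n = 3). The best MMP9 peak, whose fold is given, lay elsewhere in CIS replicate 3 than in replicates 1 and 2. SMAD7, an inhibitor of TGF-beta signalling, had a fold of 4.29 ± 1.33 (SD, n = 3). In the opposite direction stood KLF6, an injury-induced transcription factor of the tubule, and MDM4, an inhibitor of p53, with folds of 5.36 ± 0.782 and 5.17 ± 1.18 (SD, n = 3 each). These genes stand for no tested group, and 0 of the annotation terms passed.

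The first pattern is the 661 regions and 218 genes found in one group alone: 1 of the 10 divisions of the libraries, the real one, gave as many; the highest of the others gave 390 and 107, and 10 divisions are too few for a share under 0.05. Taken alone, the 58 knockdown-alone genes lay within the range of single sets of the other divisions (16 to 63). The 235 knockdown-alone regions equalled the top of theirs (122 to 235). At the listed lengths the sums thus stood apart mainly through the cisplatin direction. With equal list lengths, 347 regions were found in the cisplatin lists alone and 266 in the knockdown lists alone. The other divisions then gave at most 385 regions in all, with a ratio of at most 1.43, so their single sets stayed below 266. For regions, both directions stood apart at equal lengths. In the cisplatin direction 42 regions had a score of at least 200 in all 3 lists and 0 peaks in the knockdown lists. Weak peaks that cross the listing threshold by chance are thus not the whole source there. Single sets of the other divisions held 4 to 20 such regions. With 10 divisions and a limit chosen after the data were seen, these counts cannot separate a group difference from differences between single libraries. A high score did not mean a low FDR: the SIX5 region, among the 42, had 53.4% in CIS replicate 1 (score 252). The knockdown direction had 5 such regions, within the range of 4 to 20, so threshold crossing stays open there. Peaks placed at another position of the same gene, as in PTMS, are not the whole source either: 6.66% of the 661 regions and 23.4% of the 47 strong regions of both directions had another region of their gene within 10 kilobases that favoured the other group by at least 2 libraries (95% exact binomial intervals 4.88 to 8.83 and 12.3 to 38.0). For the 74.3% of regions whose lowest score was under 100, threshold crossing cannot be told apart from a change, since depth is unknown, and a change of m5C after loss of NSUN7, a change of RNA level and any unrecorded processing difference between the groups stay open.

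The second pattern is the excess of the cisplatin direction, 1.81 times for regions and 2.76 times for genes (for regions 1.03, 1.09 and 1.17 without knockdown replicate 1, 2 or 3 and 2.14, 1.67 and 2.21 without cisplatin replicate 1, 2 or 3, where presence in 2 libraries of the shortened group was enough; for genes 2.02 to 2.57). Equal list lengths lowered the excess but did not remove it. With 14964 peaks in each list the cisplatin share was still 56.6% of regions (95% exact binomial interval 52.6 to 60.6) and 66.3% of genes (59.5 to 72.7). These intervals treat neighbouring regions as independent and leave out the spread between libraries. They therefore cannot decide whether an excess beyond list length exists. Differences between single libraries stay open for genes, since another division reached 3.75 times. Its larger side held 2 cisplatin libraries, and divisions with 2 knockdown libraries on the larger side reached 1.58. With equal lists, however, another division reached 2 times for genes, against 1.97 in the real division. For regions the highest other ratio was 1.70, or 1.43 against 1.30 with equal lists, too close for a distinction. For regions and genes alike, the excess cannot be told apart from such differences.

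The third pattern is that some regions of one direction fall in the same genes. In the cisplatin direction 5 genes held 3 or more of the 426 regions, and in the knockdown direction 5 held 3 or more of the 235. Single sets of the other divisions, with 122 to 235 regions each, had 0 or 1 such gene. These genes held 31 cisplatin-alone and 16 knockdown-alone regions. Most regions were alone in their gene, since the 426 lay in 377 genes and the 235 in 218. Neighbouring regions of a gene may be parts of 1 stretch of spliced RNA, since exons were not analysed here, and are then not separate. One hypothesis is a change along the whole transcript, as in CACNA1G. The other regions of genes with a cisplatin-alone region had 0.192 more cisplatin than knockdown libraries with a peak than other genes did (permutation of genes, p = 5e-05). For genes with a knockdown-alone region the excess was -0.299 (permutation of genes, p = 1e-05, the smallest possible with 100000 permutations). Both go with a change along the transcript. These p-values permute genes and not libraries, so they do not measure the spread between the 3 libraries of a group. However, other divisions of the libraries gave an excess of up to 0.231 in the direction of their regions, above the 0.192 of the cisplatin direction and below the 0.299 of the knockdown direction (lowest 0.0104). Each of those divisions keeps 2 libraries of a group together, so a difference between the groups can add to their excess, and RNA level, which the input libraries would show, stays open.

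A single peak of MED12L in the second knockdown list, 127 bases long at chromosome 3, 151188354 to 151188480, had an authors' fold of 11208, where the next highest fold of any peak was 256.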
